A study of Danio rerio with 3 samples.

How the data were processed

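DNA methylation was measured by reduced representation bisulfite sequencing in 3 libraries of cells sorted from zebrafish embryos. In this assay genomic DNA is cut with a restriction enzyme that recognises CpG-containing sites, and the short fragments are treated with bisulfite, so that unmethylated cytosines are read as thymine. Bisulfite does not tell 5-methylcytosine from 5-hydroxymethylcytosine, and the level given here is the sum of both. Per the labels, neutrophils were sorted by an mpx:GFP reporter and myeloid progenitors by a pu.1:GFP reporter, and DNA was extracted with a column kit.

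For each library the authors deposited a table of CpG calls with the coverage count of each strand-specific cytosine, a whole number of reads with a C or T call. The same deposited tables give the percent of those reads called C and the percent called T. The tables have no header, and their columns were recognised by their layout and values. The C and T percentages summed to 100 and coverage multiplied by the percent of C gave a whole number of methylated reads at all listed sites, both within a tolerance of 1e-06. The lowest listed coverage was 1 read. The submitters' processing notes name bcl2fastq, Bismark and methylKit, without versions. Trimming, mapping parameters and the handling of duplicate reads are not given in the sources used here. Duplicates cannot be recognised in RRBS by position, so PCR copies may be counted as separate reads. The Wilson intervals described below cover at most counting error, since they treat calls, or sites for a share of sites, as independent. The genome build is not given in the sources used here either, and coordinates are printed as the deposited tables give them, with 1-based positions. The authors also deposited a sheet with 2 totals of differentially methylated regions, without positions, region definition or thresholds.

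From these tables, methylated and unmethylated read counts were rebuilt for each site on chromosomes 1 to 25. The 3 libraries held 60514633, 61076662 and 59427694 CpG calls for WT neutrophils, tet2/3DM neutrophils and WT myeloid progenitors. Sites with fewer than 10 reads in a compared library were left out. Levels were compared over the 863696 sites with 10 or more reads in all 3 libraries. The read-weighted level is the share of C among all calls at these sites, with a Wilson 95% interval. The site mean weights every site equally, and the 95% interval of a difference of site means came from 1000 bootstrap draws of 1-Mb windows. That interval covers variation along the genome and not variation between embryos.

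Each site was tested with a two-sided Fisher's exact test on the read counts of 2 libraries. A site was called when its Benjamini-Hochberg adjusted p was under 0.01 and its level differed by at least 25 percentage points. The same rule was applied to summed reads of non-overlapping tiles of 1000 bp with at least 3 sites. Reads over neighbouring CpGs of 1 molecule are not independent, so tile p-values are too small and the size threshold carries the call. For the same reason Wilson intervals of calls summed over sites, such as those of tiles, are too narrow even for counting error. Each group had 1 library. A Fisher test here compares 2 libraries and not 2 genotypes or cell types, and no replicate error could be given.

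CpG density was counted as the number of CpG dyads listed in any library within a window of 201 bp centred on the site. A dyad is the pair of cytosines on opposite strands of 1 CpG. Sites lost or gained between WT progenitors and WT neutrophils were followed in tet2/3DM neutrophils after the WT neutrophil reads of each site had been divided at random into 2 equal parts. Part A served to call the site, with at least 10 reads per part, and part B served as the level that tet2/3DM was set against. Uncalled sites of like part A level and coverage were the matched background. The design also planned promoter values, annotation classes, 15 gene lists and named genes. These need a gene annotation in the coordinates of the tables and were not analysed here. The rule for named items fixed before the data were examined then asked for the 10 called tiles with the largest increase and the 10 with the largest decrease among tiles with at least 10 sites in both libraries. In a named tile, the level of the library outside the comparison was taken over its own sites of 10 or more reads. Those sites can differ from the sites of the compared libraries. Chromosome 4 from 28 Mb, the 1-Mb windows and the search for opposite strands that differed by 50 points or more were chosen after the data had been seen.

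The calling steps were tested on simulated data with the real coverages. Levels were shifted upward only, at sites and tiles of 50% or less, so falls and shifts from higher levels were not simulated. Reads were drawn with counting error alone, without PCR copies or deviations of a library. For tet2/3DM against WT neutrophils, 52.1% of 10000 sites shifted by 30 points and 81.2% of those shifted by 50 points were called among 1041106 tested sites. Of 1021106 unchanged sites 8 were called. For tiles, 86.5% of 200 shifted by 30 points and 95.5% of 200 shifted by 50 points were called among 133459 tested tiles. For WT neutrophils against WT myeloid progenitors, 54.25% and 83.1% of sites were called at these sizes among 904530 tested sites, and 87.5% and 97.5% of tiles among 117265. With no tet2/3DM effect simulated, sites called lost had a mean tet2/3DM difference of 0.011 points with divided reads and of 2.82 points with the same reads in both comparisons.

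Alternatives covered the coverage minimum (5 or 20 reads), the size threshold, summed strands, reads thinned to the lower coverage, Bonferroni adjustment, tile width, tile site number, median site differences, the weighting of sites, sites of each library alone and removal of the top 0.1% of coverage. Removal of discordant dyads and a requirement for a moved neighbouring dyad were added after the data had been seen. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.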

Results

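CpG methylation was compared in 3 libraries of sorted zebrafish embryo cells, with 1 library in each of 3 groups. Neutrophils were taken at 2 days post-fertilization from wild-type (WT) embryos and from embryos of the tet2/3DM genotype, a tet mutant. They were sorted by a reporter of mpx, the gene of the granule enzyme myeloperoxidase. Myeloid progenitors were taken from WT embryos at 17.5 hours post-fertilization by a reporter of pu.1, a transcription factor that directs myeloid development. Tet enzymes oxidise 5-methylcytosine, a step in the removal of DNA methylation. The design asks how methylation differs between mutant and WT neutrophils and how it changes from WT progenitors to WT neutrophils. There were no replicates, so each difference is one between 2 libraries, and intervals cover at most counting error or variation along the genome.

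The depth of the libraries was alike. WT neutrophils had 60514633 CpG calls, tet2/3DM neutrophils 61076662 and WT progenitors 59427694. At least 10 reads covered 1149466, 1170931 and 1012484 sites, with medians of 39, 39 and 36 reads at those sites. The progenitor calls were spread over more sites, and 13.6% of its 7449467 listed sites had 10 or more reads, against 27.3% of 4211316 in WT neutrophils and 30.8% of 3800792 in tet2/3DM neutrophils.

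All 3 cell populations had mostly methylated CpGs, and WT neutrophils stood apart by sites at intermediate levels. Over the 863696 shared sites, 10.004% of sites lay between 20% and 80% in WT neutrophils, against 4.86% in tet2/3DM neutrophils and 5.06% in WT progenitors. Sites above 80% made up 72.8% in WT neutrophils, 78.3% in tet2/3DM neutrophils and 77.8% in progenitors. The unmethylated class below 20% was nearly constant, at 17.2%, 16.8% and 17.2%. The mean over sites was 74.5% in WT neutrophils, 77.0% in tet2/3DM neutrophils and 77.9% in progenitors.

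**Figure D1:**
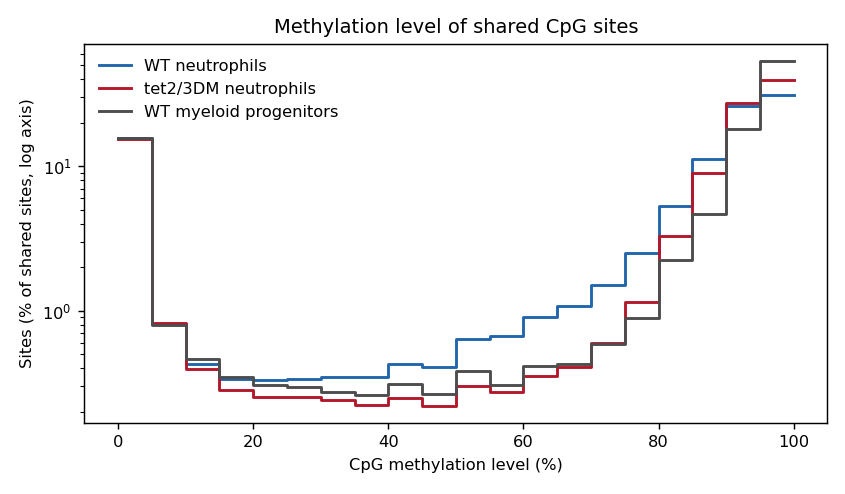
Share of the 863696 shared CpG sites (vertical, log axis, percent) by methylation level (horizontal, percent, in steps of 5 points) in each of the 3 libraries, drawn as step lines. WT neutrophils have 10.004% of sites between 20% and 80%, above the 4.86% of tet2/3DM neutrophils and the 5.06% of WT progenitors.

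Read-weighted levels were lower than site means in every library. They were 70.8% in WT neutrophils (Wilson 95% interval 70.82% to 70.85%), 73.1% in tet2/3DM neutrophils and 69.6% in WT progenitors. The direction from progenitors to WT neutrophils depended on this weighting, with +1.204 points by reads and -3.38 points by sites. Unmethylated sites took more reads in the progenitor library, with a mean of 76.5 reads below 20% and 45.5 reads above 80%, against 68.1 and 53.1 reads in WT neutrophils.

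Methylation was higher in tet2/3DM than in WT neutrophils across the genome. The site mean was higher by 2.51 points (95% interval 2.41 to 2.61) and the read-weighted level by 2.32 points. Each of the 25 chromosomes had a higher mean in tet2/3DM, by 1.96 points on chromosome 2 to 3.06 points on chromosome 22. The median site difference was 0.38 points, and the highest 1% of sites differed by 45.8 points or more. Sites at intermediate levels in WT progenitors differed most. Where progenitors had 40% to 60%, tet2/3DM neutrophils averaged 63.6% and WT neutrophils 51.2%, a difference of 12.4 points (11.5 to 13.3). Where progenitors had under 20% the difference was 0.96 points, and at 90% or more it was 2.14 points.

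**Figure D2:**
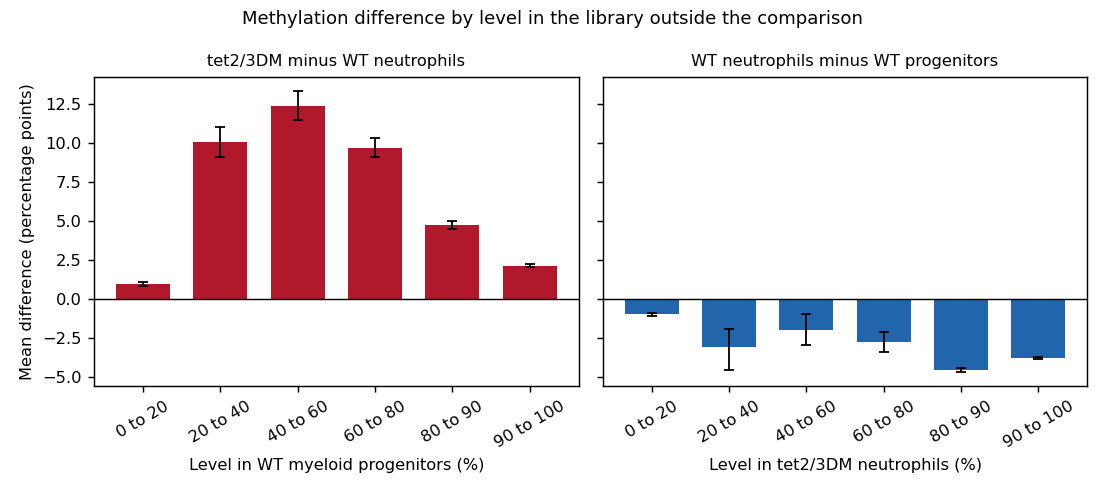
Mean methylation difference (vertical, percentage points) between tet2/3DM and WT neutrophils by level in WT progenitors (left panel), and between WT neutrophils and WT progenitors by level in tet2/3DM neutrophils (right panel). Bars are means over sites and error bars are 95% intervals from bootstrapped 1-Mb windows. The genotype difference reaches 12.4 points at 40% to 60%, and the cell type difference is below 0 in every class.

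Of 1041106 sites tested between tet2/3DM and WT neutrophils, 21264 were higher and 2543 were lower in tet2/3DM (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.01, 25 points or more). The higher sites were partly methylated in WT neutrophils and nearly fully methylated in tet2/3DM, with medians of 49.8% and 94.2%. Neighbouring CpG dyads within 50 bp moved with them, with a median difference of 32.2 points and 91.1% of the same sign. Lower sites had medians of 80% in WT and 25% in tet2/3DM neutrophils. Dyads within 50 bp of them had a median difference of -4.00 points, while the opposite strand of the same CpG had -30.4 points over 356 sites. A dyad within 100 bp moved the same way by 10 points or more at 47.2% of the lower sites (1201) and at 84.3% of the higher sites (17932).

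The authors' deposited table lists 21338 hyper- and 2554 hypomethylated regions for WT and tet2/3DM, without stating direction, cell type or region size. Those totals lay within 74 and 11 of the single-site counts. Called tiles of 1000 bp were far fewer, with 3688 higher and 228 lower of 133459 tested. Higher tiles had a median of 56.4% in WT and 93.3% in tet2/3DM neutrophils.

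The genotype difference varied with CpG density and was above 0 in every density class. In sites with 8 to 11 dyads in 201 bp, tet2/3DM exceeded WT neutrophils by 3.13 points (2.98 to 3.29) and 2.73% of tested sites were called higher. In the densest class, with 18 or more dyads and a WT neutrophil level of 36.8%, the difference was 0.38 points (0.25 to 0.52) and 0.50% were called higher. Sparse sites with 1 or 2 dyads differed by 1.88 points.

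The 10 tiles with the largest increase had 1.96% to 25.5% methylation in WT neutrophils and 82.0% to 97.0% in tet2/3DM neutrophils. The first lay on chromosome 22 at 18324001 to 18325000, with 89.6% in tet2/3DM (95% interval 87.0% to 91.6%, 670 calls) and 5.12% in WT neutrophils (3.37% to 7.70%, 410 calls), and 46.4% in WT progenitors. On chromosome 10 at 28315001 to 28316000 the levels were 82.0% and 1.96%, with 54.0% in progenitors. Chromosome 23 held 3 of the 10, at 23116001, 23150001 and 34411001, with 92.8%, 87.1% and 89.2% in tet2/3DM against 10.5%, 10.7% and 14.9% in WT neutrophils. On chromosome 19 at 46013001 the levels were 95.3% and 14.97%, and on chromosome 18 at 30213001 they were 93.7% and 18.8%. The other 3, on chromosome 10 at 10919001, chromosome 5 at 14719001 and chromosome 22 at 11149001, differed by 72.5, 72.3 and 71.5 points. Progenitor levels at these 10 tiles ranged from 8.07% to 89.4%, and the largest adjusted p was 3.63e-138 (Fisher's exact test between libraries).

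Of the 10 tiles with the largest decrease in tet2/3DM, 7 lay on chromosomes 11 and 7. Chromosome 11 held 4 of the 10, at 39661001, 42933001, 44041001 and 41512001. The tile at 41512001 lost its call at a coverage minimum of 20 reads, with -6.37 points, and by the median of its sites, with -13.2 points. The tile at 39661001 had 18.1% in tet2/3DM (15.07% to 21.7%, 518 calls), 84.1% in WT neutrophils (80.4% to 87.2%, 434 calls) and 94.6% in WT progenitors. Levels at 42933001 and 44041001 were 10.8% and 16.7% in tet2/3DM, 54.9% and 58.2% in WT neutrophils, and 91.5% and 96.7% in progenitors. Chromosome 7 held 3, at 29815001 with 11.1% against 61.5%, and at the adjacent tiles 46819001 and 46820001 with 4.33% against 38.7% and 3.71% against 37.2%. The remaining tiles, on chromosome 22 at 643001, chromosome 1 at 19939001 and chromosome 2 at 6351001, fell by 36.9, 34.2 and 33.4 points. Without dyads whose strands differed by 50 points or more, the chromosome 22 tile kept fewer than 3 sites and was not tested. Progenitor levels at these 10 tiles ranged from 14.5% to 96.7%. Just 30 lower tiles had 10 or more sites, against 582 higher ones.

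From WT progenitors to WT neutrophils, more sites lost than gained methylation. The site mean went from 77.9% in progenitors to 74.5% in neutrophils, a difference of -3.38 points (95% interval -3.46 to -3.30), and was lower in neutrophils on each of the 25 chromosomes. At sites of 90% or more in tet2/3DM neutrophils the mean difference was -3.81 points, and at 40% to 60% it was -1.98 points. A uniform loss of C calls in WT neutrophils would shrink with the level, as the difference does between these classes. At 20% to 40% in tet2/3DM neutrophils the difference was -3.12 points (-4.57 to -1.94), so the classes do not all follow that order. The explanation was not tested for this comparison and stays open. Of 904530 tested sites, 14786 were lower and 5952 higher in neutrophils by the same rule. Lower sites went from a median of 94.4% in progenitors to 48.6% in neutrophils, and dyads within 50 bp had a median difference of -26.4 points. Higher sites went from 15.8% to 77.8%, and their neighbours differed by 4.98 points at the median. Of 117265 tiles, 2641 were lower and 548 higher. Cell type, stage and reporter differ together in this comparison, and the read-weighted level has the opposite sign, as given above.

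The tile with the largest loss, on chromosome 8 at 7733001 to 7734000, had 97.4% in WT progenitors (95% interval 95.8% to 98.4%, 587 calls), 6.83% in WT neutrophils (5.62% to 8.29%, 1376 calls) and 9.08% in tet2/3DM neutrophils. The other 9 tiles differed in their tet2/3DM levels. On chromosome 18 at 30213001, the tile also listed for the genotype comparison, progenitors had 87.8%, WT neutrophils 18.8% and tet2/3DM neutrophils 93.5%. On chromosome 9 at 46272001 and chromosome 13 at 30402001 progenitors had 96.8% and 97.3%, and tet2/3DM neutrophils 94.4% and 94.6%, while WT neutrophils fell by 62.2 and 59.1 points. Tiles on chromosome 10 at 38206001 and chromosome 21 at 27214001 had 80.8% and 90.4% in tet2/3DM neutrophils and fell by 65.9 and 59.0 points in WT. The tet2/3DM level was close to that of WT neutrophils or lower on chromosome 5 at 39617001, with 31.4% against 37.7%, and on chromosome 6 at 634001, with 5.05% against 4.99%. It was intermediate on chromosome 4 at the adjacent tiles 73311001 and 73312001, with 57.7% and 51.3%. These 4 fell by 58.8, 61.4, 58.3 and 61.9 points in WT neutrophils.

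The 10 tiles with the largest gain from progenitors to WT neutrophils rose by 61.05 to 78.5 points. On chromosome 6 at 36379001 to 36380000 the level was 12.4% in progenitors (9.76% to 15.5%, 502 calls), 90.9% in WT neutrophils (86.3% to 94.0%, 219 calls) and 97.2% in tet2/3DM neutrophils. On chromosome 10 at 27425001 it was 0.38% in progenitors, 75.2% in WT and 73.1% in tet2/3DM neutrophils. Tiles on chromosomes 11, 20, 25 and 4, at 42166001, 45653001, 34803001 and 10713001, had 87.0%, 90.2%, 79.9% and 75.4% in WT neutrophils and 79.9%, 81.8%, 92.6% and 77.7% in tet2/3DM. Chromosome 17 held a pair, at 733001 and 19316001, with 95.1% and 66.1% in WT and 94.99% and 34.4% in tet2/3DM neutrophils. Intermediate tet2/3DM levels were found on chromosome 9 at 4985001, with 80.6% in WT and 47.5% in tet2/3DM, and on chromosome 18 at 11954001, with 79.2% and 55.0%.

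Many sites that lost methylation between WT progenitors and WT neutrophils were methylated in tet2/3DM neutrophils, and sites that gained it were on average methylated in both neutrophil libraries, with a minority low in tet2/3DM. With WT neutrophil reads divided into 2 parts, 10853 sites were called lost on part A. At these sites progenitors averaged 89.9%, WT neutrophils 48.1% on part B and tet2/3DM neutrophils 76.1%. In 55.9% of them (Wilson interval 55.0% to 56.9%) tet2/3DM exceeded part B by 25 points or more, against 34.3% of uncalled sites matched on WT level and coverage. The share was 5.91% of uncalled sites matched on progenitor level and coverage. Those sites stayed methylated in WT neutrophils, which leaves tet2/3DM little room to exceed them, so the 5.91% is low by construction. The mean difference was 27.99 points at lost sites and 15.9 points at matched sites. At the 4174 sites called gained, progenitors averaged 18.2%, WT neutrophils 69.2% and tet2/3DM neutrophils 66.4%. There the share with tet2/3DM lower than part B by 25 points or more was 17.01% (15.9% to 18.2%), against 1.86% of matched sites, and the mean difference was -2.81 points, against 9.73 points at matched sites. Dividing the reads removes counting error shared by both comparisons, not deviations of the WT neutrophil library itself. The Wilson intervals of the shares take sites as independent. Nearby sites moved together, so these intervals are too narrow and do not cover variation along the genome.

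Measured from the WT neutrophil library, 8312 sites were higher both in tet2/3DM neutrophils and in WT progenitors. Independent lists of 19958 and 14626 sites among 863696 would share 338. Simulated unchanged libraries shared 0, but they hold counting error alone, under which almost no site is called, and give no background for a deviation of the shared library. The covariance of the 2 differences was 60.1 squared points, against 16.0 in the simulation, and their correlation across sites was 0.50, against 0.47. Among tiles of 1000 bp tested in both comparisons, 1792 were called in both, of 3183 higher in tet2/3DM and 2518 lower in WT neutrophils than in progenitors, against 71.1 for independent lists. How much of these overlaps comes from the shared library was not separated. In the other direction 729 sites were lower in both, against 16.2 for independent lists.

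Of the 19721 sites higher in tet2/3DM than in WT neutrophils that progenitors also covered, 54.6% were above 80% in progenitors. Those averaged 93.2% in progenitors, 54.5% in WT and 94.5% in tet2/3DM neutrophils. A further 34.2% were between 20% and 80% in progenitors, with averages of 54.0%, 39.7% and 88.2%. The remaining 11.2% were below 20% in progenitors and averaged 5.04%, 18.1% and 67.8%. Since the sites were picked as higher in tet2/3DM than in WT neutrophils, these averages describe the picked sites alone. Over all 863696 shared sites, 77.8% were above 80% in progenitors, 5.06% between 20% and 80% and 17.2% below 20%. The picked sites were more often at intermediate progenitor levels, and less often above 80%, than shared sites at large. A site called higher cannot be near full methylation in WT neutrophils, and the 2 WT libraries correlated at 0.95 across sites. The selection alone thus favours this contrast, and nothing is concluded from it.

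**Figure D3:**
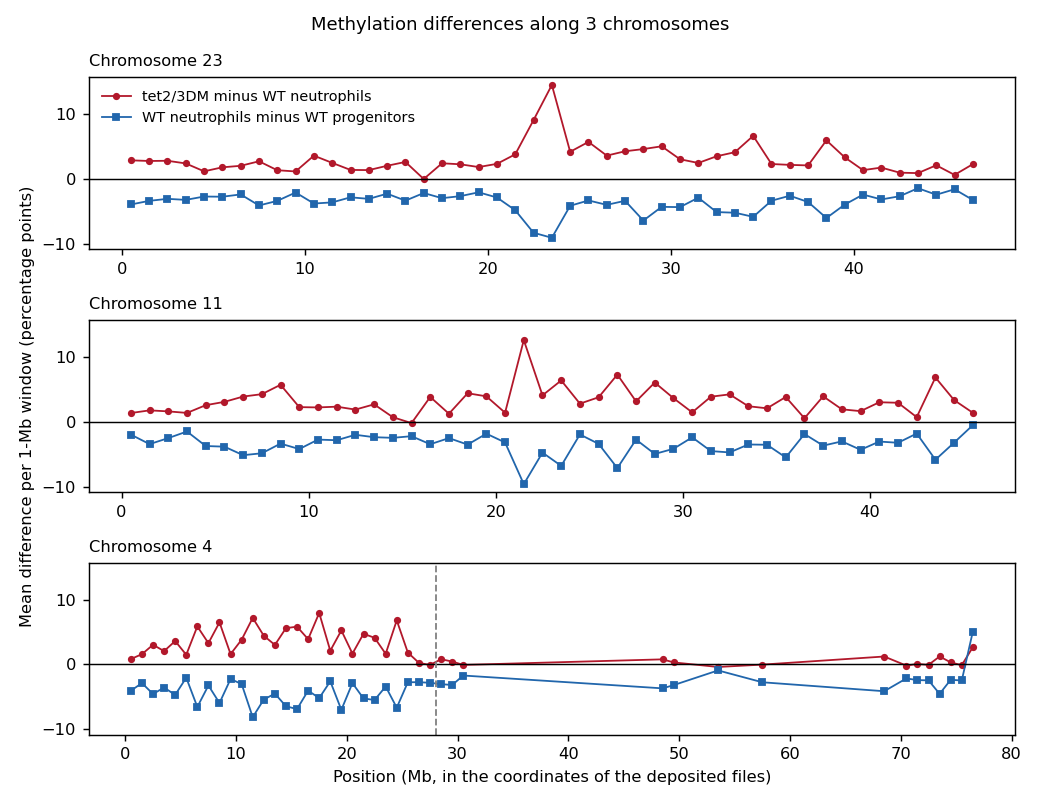
Mean methylation difference per 1-Mb window (vertical, percentage points) along chromosomes 23, 11 and 4 (horizontal, Mb) for tet2/3DM minus WT neutrophils (circles) and WT neutrophils minus WT progenitors (squares), for windows with at least 200 shared sites. The genotype difference peaks at 14.4 points on chromosome 23 and 12.55 points on chromosome 11, and lies near 0 in most windows of chromosome 4 beyond the dashed line at 28 Mb.

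The genotype difference varied along chromosomes. Of 1316 windows of 1 Mb with at least 200 shared sites, 1294 had a higher mean in tet2/3DM, with a median difference of 2.23 points and the lowest and highest 1% of windows beyond -0.17 and 8.33 points. In the window from 23 Mb on chromosome 23, tet2/3DM had 79.1%, WT neutrophils 64.6% and WT progenitors 73.7%, and 22 of 108 tiles were called higher. In the window from 21 Mb on chromosome 11, the levels were 89.4%, 76.8% and 86.4%, and 17 of 107 tiles were called higher. These windows were picked by their values. Nearby CpGs moved together over short distances, with a correlation of 0.52 across pairs of sites 2 to 50 bp apart, 0.47 at 51 to 100 bp and 0.08 at 501 to 1000 bp. Sites are not independent replicates in these correlations.

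Opposite strands of a CpG served as a comparison within each library. Both strands had 10 or more reads at 127282 dyads in WT neutrophils, 131089 in tet2/3DM neutrophils and 112933 in progenitors, and the rule for sites called 9.09%, 9.86% and 9.84% of them different. In WT neutrophils 10943 dyads differed by 50 points or more, and sites in such dyads of any library made up 2.41% of those tested between genotypes. Dyads low on the reverse strand were followed within 200 bp by dyads low on the forward strand in 3658 cases in WT neutrophils, and the other order was found in 33. Because of this order along the DNA, seen only after the comparison had been planned as a background of counting noise, strand differences are not counting noise alone and are given without being set against the site calls.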

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

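Of the tests in this part, that of unequal coverage was set before its result was seen, and the others after. Mitochondrial CpGs, which no comparison used, gave C calls in each library above the limit that a count of 0 allows. Apparent methylation was 0.285% in WT neutrophils (395 of 138635 calls, Wilson 95% interval 0.258% to 0.314%, limit 0.0022%), 0.293% in tet2/3DM neutrophils (459 of 156362 calls, limit 0.0019%) and 0.286% in WT myeloid progenitors (660 of 230910 calls, limit 0.0013%). The 3 intervals overlapped.

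Sites higher in tet2/3DM than in WT neutrophils outnumbered lower ones 8.36 to 1. Incomplete bisulfite conversion of the tet2/3DM library was argued against by mitochondrial CpGs, which differed by 0.0086 points, and C-to-T variants of the WT strain by other dyads within 50 bp of the higher sites, which moved by 32.2 points at the median. Unequal coverage was argued against by a ratio of 8.78 after thinning, and a uniform loss of C calls in the WT library by the difference of 12.4 points at sites of 40% to 60% in progenitors, where a loss scaled from sites of 90% or more would give 1.45 points. Another mix of cell types in the WT sort cannot be told apart from demethylation in part of the neutrophils, since the higher sites had a median of 49.8% in WT neutrophils and either gives such a level. An effect of the tet2/3DM genotype stays open and was not tested, since there is 1 library per genotype. Parents, clutch and the cell mix of the tet2/3DM sort, which was not examined, are not told apart from such an effect.

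Sites lower in tet2/3DM than in WT neutrophils were a mixed set, in which 47.2% had another dyad within 100 bp that moved the same way by 10 points or more. C-to-T variants of the mutant fish, read as unmethylated CpGs, would lower both strands of 1 CpG and not its neighbours. At lower sites with a neighbour and none that moved, the opposite strand had a median difference of -17.9 points over 126 sites (95% bootstrap interval -27.2 to -3.87), too wide to decide, so variants stay open there. Fill-in at fragment ends stays open too. Of the 444 lower sites with both strands covered, 19.6% lay in discordant dyads, against 9.72% of all such tested sites and 6.16% of 5045 higher ones. Discordance was scored in any library, so a lower call on 1 strand alone can itself make a dyad discordant. The 19.6% therefore does not decide. A loss of methylation that comes with the genotype was not tested and stays open.

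In each library, opposite strands of some CpGs differed by 50 points or more. End-repair fill-in, in which fragment ends are completed with unmethylated cytosines, may account for many of them. Dyads low on the reverse strand were followed within 200 bp by dyads low on the forward strand 110.8 times as often as the other way round in WT neutrophils, the lowest ratio of the 3 libraries (3658 against 33), at a median spacing of 44 bp. Hemimethylation of the dyads in the cells gives no such order and was argued against by the same ratio as the main source. No biological group difference was tested for this pattern.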

How the results depend on the processing

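Removal of discordant dyads, the moved-neighbour rule and the alternatives for density classes and chromosome 4 were chosen after seeing the data. No result of the genotype comparison changed direction under the alternatives run. Among the results of the genotype and cell type comparisons, only the read-weighted change from WT progenitors to WT neutrophils did, at -3.38 points with equal site weights. The comparison of tet2/3DM neutrophils with WT progenitors was not put through the alternatives. Its sign also depended on the weighting, with +3.52 points by reads and -0.87 points by sites. At the depth of these libraries the level intervals are narrow, so nearly every setting moved a level past its interval. Levels in WT neutrophils, tet2/3DM neutrophils and WT progenitors were 71.7%, 74.0% and 70.4% at 5 reads, 69.1%, 71.3% and 68.1% at 20 reads, 74.5%, 77.0% and 77.9% with equal weights, 72.6%, 75.2% and 70.6% over each library's own sites, 71.4%, 73.8% and 70.6% without the top 0.1% of coverage, and 71.1%, 73.4% and 69.8% without discordant dyads. The genotype difference was 2.34 points at 5 reads, 2.22 at 20 reads, 2.51 with equal weights, 2.64 over own sites and 2.43 without the top coverage. The cell type difference was 1.345, 0.97, -3.38, 1.99 and 0.80 points in that order, and 1.25 without discordant dyads. The cause of the sign change from WT progenitors to WT neutrophils was not tested beyond the reads per class given in the results.

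Site counts for tet2/3DM against WT neutrophils were 11516 higher and 1532 lower at 40 points and 7238 and 831 with Bonferroni adjustment, both stricter by construction, and lower sites with a moved neighbour numbered 1201. For WT neutrophils against progenitors, 7887 sites were lower at 40 points, 2526 higher and 4288 lower with Bonferroni adjustment, and 3007 higher sites had a moved neighbour. Tile counts for the genotypes were 582 higher and 30 lower with at least 10 sites, and 7384 and 525 at 15 points. For the cell types they were 77 higher and 317 lower with at least 10 sites, and 1232 and 6466 at 15 points. The excess of lost sites higher in tet2/3DM over matched sites was 21.7 points, 29.3 points without dividing the reads and 50.03 points when matched on the progenitor level. The last setting compares with sites that stayed methylated in WT neutrophils. The other 66 alternatives of counts, differences and shares stayed within 1.5 times or within their interval. The tile on chromosome 22 at 643001 kept fewer than 3 sites without discordant dyads and was not tested there. At 20 reads the same held for the tile on chromosome 6 at 36379001. It also held at 20 reads for the tile on chromosome 18 at 30213001 between cell types. Of the 197 alternatives of named tiles that were tested, 195 were called the same way. The other 2 were those of the tile on chromosome 11 at 41512001, which fell short of the threshold with -6.37 points at 20 reads and -13.2 points by the median of its sites. All 42 alternatives of density classes and chromosome 4 stayed within an interval made with fewer than 1000 bootstrap draws. At 20 reads the class of 12 to 17 dyads, WT neutrophils against WT progenitors, had -1.837 points. That value lies just outside the interval of 1000 draws for this class, -2.096 to -1.845. Promoter and gene list alternatives were not run, since no annotation in these coordinates was used here. No paired analysis was possible because each group has 1 library.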

Other observations

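The windows, chromosomes and parts of chromosomes described here were picked after their values had been seen. Set against WT progenitors, tet2/3DM neutrophils differed in the direction opposite to WT neutrophils at the level of called sites. Of 898999 tested sites, 11813 were higher and 5437 lower in tet2/3DM neutrophils, and of 116458 tiles, 1444 were higher and 513 lower, by the same rules as in the other comparisons. The site mean was still below that of progenitors, by -0.87 points (95% interval -0.93 to -0.80), while the read-weighted level was higher by 3.52 points. At sites of 20% to 40% in WT neutrophils, tet2/3DM averaged 52.1% and progenitors 43.0%. At sites of 90% or more in WT neutrophils they averaged 94.5% and 96.0%.

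Chromosome 4 from 28 Mb took little part in the genotype difference. Over its 13844 shared sites tet2/3DM had 86.2% and WT neutrophils 85.9%, a difference of 0.32 points (-0.05 to 0.75), against 3.43 points on the rest of that chromosome. Sites called higher made up 0.21% of those tested there and 2.08% elsewhere. The long arm of zebrafish chromosome 4 is known to be rich in repeats, and the border at 28 Mb was not placed by an annotation. At the end of this chromosome, from 76 Mb, 1029 shared sites averaged 61.1% in progenitors, 66.2% in WT and 68.9% in tet2/3DM neutrophils. There 9.29% of 1076 tested sites were higher in WT neutrophils than in progenitors, and 0.48% of 1244 differed upward between genotypes.

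Sites called lower and sites called higher in tet2/3DM were both spread unevenly. By chromosome, lower sites made up 0.10% of tested sites on chromosome 4 to 0.62% on chromosome 1, a 6.38-fold range. Higher sites made up 1.32% on chromosome 4 to 2.98% on chromosome 22. The 67 windows of 1 Mb with the highest share of lower sites held 29.4% of them and 4.36% of tested sites. With tiles of 1000 bp, each kept whole with its calls, placed at random, the windows ranked in the same way held 23.2% on average and at most 24.9% in 100 draws. For higher sites the observed share was 17.3%, against 10.6% on average and at most 11.8% at random, and the difference between both kinds of call was not tested. Clusters of calls that span more than 1 tile are not held together by this placement. On chromosome 7 from 46 Mb, 36 of 757 sites were lower, and on chromosome 15 from 9 Mb, 12 of 383. The chromosome 7 window holds the adjacent lower tiles at 46819001 and 46820001, with 25 and 16 sites, so its count may reflect 1 locus.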
